A study of Mus musculus with 20 samples.

How the data were processed

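Total RNA from livers of 20 male mice was extracted with RNeasy columns, checked on a Bioanalyzer, labelled as biotinylated cRNA and hybridised to Illumina mouse BeadChips, per the labels' protocols. The labels put 5 arrays in each of 4 groups, made of wild-type or ApoE-/- genotype and antagonist or no treatment, and the groups were taken from those labels. They number the replicates of a group and do not state that each came from its own animal, so p-values measure the spread between these samples, which may be partly technical.

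The deposited non-normalized table gives, for 45281 probes and each array, a signal intensity on a linear scale that the authors neither background-subtracted nor quantile-normalized, as its values show. Array means were equal within 4 sets of arrays (326.99, 399.38, 341.05 and 358.13, by genotype and batch), so the arrays had been scaled within those sets before deposit by a step that the sources used here do not describe. Beside each intensity the authors deposited a detection p-value for the probe on that array. GenomeStudio and BeadStudio are named in the submitters' processing notes, with versions not given in the sources used here. The deposited series matrix holds the authors' processed intensity values of the same arrays on a linear scale. On every array these followed the non-normalized signal in rank (Spearman correlation of 1), with medians of 103.60 to 103.62 and equal quartiles, no centring of genes and no ratio between samples. Scale and direction were thus settled, while the normalization that gave them stays unknown. They served as an alternative source.

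Probes were named through the platform's probe table, with symbols updated by gene identifier or accession through a RefSeq gene table of the mouse assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. Of the probes 34885 had 1 symbol, 18 several and 10378 none, and no gene was named from a probe with several.

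Signals were processed in R 4.3.3 with limma 3.58.1: neqc (normexp background correction with negative controls inferred from the detection p-values, quantile normalization, offset 16), then a filter for detection p under 0.05 on at least 5 of 20 arrays, which kept 18285 probes. For each symbol the probe with the highest mean was kept, and probes without a symbol stayed as their own entry, giving 12976 tested (10362 named, 2614 unnamed). Linear models with 4 group means were fitted to all 20 arrays, with moderated statistics and Benjamini-Hochberg adjusted p under 0.05 in each of 5 contrasts: antagonist against no treatment in wild-type and in ApoE-/- mice, the average of these, their difference, and ApoE-/- against wild type in untreated mice. A probe below detection on all arrays of a group has only a bound there, and its fold is given as at least the bright group's mean over, per array, the higher of the lowest detected signal and the probe's own. The number of arrays, 5 a group, limits the precision.

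Fixed gene lists of pathways and cell types, 39 in number, were tested with camera (correlation preset at 0.01) where at least 3 members were measured, 38 of them. They were tested again with a correlation estimated per list and with fry, which tests whether a list's genes move one way without comparing them with other genes. Over the 5 contrasts 102 list results passed with the preset and 11 with the estimated correlation, 2 of those for the difference between genotypes and 9 for the untreated genotypes. With fry 109 passed, but 14 of the 102 lost their call. For the difference between genotypes 10 of 20 kept theirs with fry. Members were counted over all genes and adjusted over the list alone. The genes named were, per contrast, a fixed panel (Apoe, Tlr7, Tlr9, Myd88, Srebf2, Cyp7a1 and Abca1, with the rest of it not reported here), the 8 largest rises and 8 largest falls past the threshold without clone or locus symbols, and up to 3 members past the threshold with the smallest adjusted p for each list. The text leaves out part of the last kind and, for the average, most of these genes. The design, lists, naming rule and most alternatives were fixed before the data were examined. Genes named in the closing section from the neighbours of Apoe, and those compared between treated genotypes, were chosen after their values were seen.

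On simulated data with 200 of 12976 genes changed, the wild-type contrast recovered 32%, 89% and 98.5% of changes of log2 0.5, 1 and 2, with 0%, 5.32% and 5.29% false calls. The difference between genotypes recovered 5.5%, 72.5% and 98%, with 8.33%, 5.23% and 4.85% false calls. Camera called all 10 shifted sets of 20 genes at a shift of 0.25 or 0.5 in the wild-type contrast and 0 of the unshifted ones among 50 sets. The simulated noise was independent between genes, so these sets do not test whether the preset correlation holds for the real lists.

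From the form of the column names the arrays were read as 2 batches. Batch 1 held replicates 1 to 3 of every group (12 arrays, slide not named). Batch 2 held replicates 4 and 5 (8 arrays: 6 on slide 1, and the 2 of untreated ApoE-/- on slide 2). Replicate numbers from the labels were tested for pairing by the correlation of deviations from group means. Same-numbered treated and untreated arrays correlated at 0.304 to 0.406 in wild-type and 0.172 to 0.426 in ApoE-/- mice. With other numbers of the same batch the mean correlation was -0.0801 to 0.356 and 0.0352 to 0.266, so batch may give part of this. The numbers were taken to pair those samples, which these values leave uncertain, and the main fits did not use that pairing. The untreated genotypes correlated at -0.00176 to 0.488 and were not taken as paired. In each of these comparisons 4 of 5 samples correlated best with their own number, so this measure does not set the untreated genotypes apart. Over the genes and probes tested, arrays correlated at 0.930 to 0.994, and no 2 held identical values. Alternatives were no background correction, the series matrix values, scaling to equal medians, no detection filter, detection on all arrays, detection p under 0.01, the replicate number or the slide as a block, a fit of the 2 compared groups, all probes, array weights, trended robust variances, a fold of at least 1.5 and leaving out each array. In the slide block the 12 arrays of batch 1, whose slides are not named, counted as 1 slide. Slide 2 held only untreated ApoE-/- arrays, so the block gave those 2 arrays no weight in contrasts of that group. A call lost with the slide as a block thus does not test the slide alone. Batch as a block and each batch alone were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.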

Results

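Liver RNA of 20 male mice on a high fat diet was measured on Illumina mouse BeadChips to ask how an antagonist of Toll-like receptors 7 and 9, endosomal sensors of nucleic acids, changed hepatic gene expression in a series concerned with cholesterol and atherosclerosis. Wild-type C57BL/6 mice and ApoE-/- mice, which lack apolipoprotein E and clear remnant lipoproteins poorly, each gave a treated and an untreated group of 5 arrays. The antagonist was injected intraperitoneally at 15 mg/kg, 3 injections weekly, between weeks 6 and 11 of age, and livers were taken at 14 weeks, after dosing had ended. The wild-type diet held 35% fat and 0.03% cholesterol by weight and the ApoE-/- diet 21% and 0.15%, so genotype and diet formula changed together.

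Apoe, the targeted gene, had a normalised log2 signal of 14.25 ± 0.36 (SD, n = 5) in untreated and 14.03 ± 0.38 in treated wild-type livers, and of 6.55 ± 0.39 and 6.00 ± 0.55 in untreated and treated ApoE-/- livers, so every array matched its genotype label. The number of probes detected was 15167 ± 604 in untreated and 17218 ± 1124 in treated wild-type livers, and 16128 ± 476 and 16753 ± 674 in untreated and treated ApoE-/- livers, of 45281 on the array. The first principal component held 49.9% of the variance and separated the 10 treated arrays (-42.7 to -6.03) from the 10 untreated ones (22.6 to 40.5). Replicates 1 to 3 and replicates 4 and 5 were read as different array batches, each holding all 4 groups. Before deposit the arrays of each genotype had been scaled apart within each batch, so genotype and scaling set changed together. Below, values after a gene are log2 changes ± SE with 5 arrays a group, and adjusted p-values are those of limma.

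Kupffer cell and other macrophage genes rose with the antagonist in wild-type livers. Among the genes with the largest rises, Fpr2, a formyl peptide receptor, rose 45.2-fold (5.50 ± 0.31), Fcgr4, an IgG Fc receptor, 43.7-fold (5.45 ± 0.29), and the C-type lectin gene Clec4a1 42.0-fold (5.39 ± 0.29), while the chemokine gene Ccl4 rose by 5.36 ± 0.32, each with an adjusted p of 1.61e-10 or less. Ms4a6d (4.83 ± 0.28), Slamf9 (4.74 ± 0.29) and Fcer1g, the adaptor of activating Fc receptors (4.52 ± 0.27), followed, and Klra17, whose probe was below detection on all untreated wild-type arrays, rose at least 21.0-fold. Fpr2, Clec4a1 and Ccl4 were detected on 3 of 5 untreated arrays and Slamf9 on 4. Of 18 measured Kupffer cell and macrophage genes 13 rose and 2 fell, the same numbers as adjusted over the list alone, with a median change of 1.86. C1qb, a complement gene of macrophages (2.90 ± 0.19), and the lysosomal protease gene Ctss (2.66 ± 0.16) were among those that rose. Among 12 genes of monocyte-derived and lipid-associated macrophages 9 rose and 1 fell, again the same numbers adjusted over the list alone, with a median of 1.56 and Lgals3 14.9-fold higher (3.90 ± 0.23). The adjusted p of these lists in camera was 5.62e-08 and 2.82e-05, and adjusted p = 0.13 for both with an estimated correlation.

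Other immune groups moved the same way in wild-type livers. Of 28 genes of Toll-like receptor signalling 16 rose and 4 fell (17 and 5 adjusted over the list alone; camera adjusted p = 0.00471; adjusted p = 0.13 with an estimated correlation). Tlr7, a target of the antagonist, rose (1.35 ± 0.18, adjusted p = 4.46e-06) from a level detected on 1 of 5 untreated arrays, and Tlr2 (2.20 ± 0.21), Myd88, the shared adaptor (0.82 ± 0.17), and Unc93b1, which carries these receptors to endosomes (2.83-fold), rose too. Tlr5, the flagellin receptor, fell by 1.81 ± 0.18, and both Tlr9 probes failed the detection filter, with detection on 0 and 1 of 20 arrays. Of 28 inflammatory cytokine, chemokine and adhesion genes 20 rose (21 adjusted over the list alone; camera adjusted p = 3.93e-08; adjusted p = 0.129 with an estimated correlation). Cxcl1 was at 3.22 ± 0.21 and Ccl5 at 2.45 ± 0.21. Of 33 interferon-stimulated genes 19 rose (20 adjusted over the list alone; camera adjusted p = 8.81e-07; adjusted p = 0.13 with an estimated correlation). Ifi27l2a was at 2.25 ± 0.16 and Oasl2 at 2.12 ± 0.16. Among 27 acute phase genes 15 rose (16 adjusted over the list alone; camera adjusted p = 1.49e-06; adjusted p = 0.13 with an estimated correlation). Apcs, serum amyloid P, was at 2.49 ± 0.22 and the metallothionein gene Mt1 2.83-fold higher. The neutrophil list had 8 of 11 members that rose (8 adjusted over the list alone; camera adjusted p = 0.000881; adjusted p = 0.149 with an estimated correlation). Class II histocompatibility genes rose in 6 of 9 (6 adjusted over the list alone; camera adjusted p = 0.00961; adjusted p = 0.256 with an estimated correlation). Of the neutrophil genes S100a8 was at 2.40 ± 0.35 and S100a9 at 2.65 ± 0.39, both detected on 4 of 5 untreated arrays.

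Genes of fatty acid oxidation fell in treated wild-type livers, as did most of the changed genes of lipid droplets, fatty acid synthesis and fasting. Of 25 genes of fatty acid oxidation and ketogenesis 21 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -1.03 (camera adjusted p = 1.08e-12; adjusted p = 0.129 with an estimated correlation). Acaa1b, a peroxisomal thiolase, fell by 2.22 ± 0.15, Ppara, the fatty acid sensor that drives these genes, by 1.29 ± 0.13 and Cpt2, which completes fatty acid import into mitochondria, by 1.03 ± 0.09. Among 14 lipid droplet genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.00128; adjusted p = 0.13 with an estimated correlation), including the droplet coat gene Plin2, which fell by 2.12 ± 0.30, and Fitm1, which fell by 1.87 ± 0.14. Of 22 genes of fatty acid and triglyceride synthesis 10 fell and 4 rose (11 and 4 adjusted over the list alone; camera adjusted p = 0.0296; adjusted p = 0.263 with an estimated correlation). Of 20 fasting and glucose genes 9 fell and 3 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.00107; adjusted p = 0.129 with an estimated correlation). G6pc, the last enzyme of glucose release, fell by 2.28 ± 0.20 and the hormone gene Fgf21 by 2.31 ± 0.34. Ppp1r3g, which targets protein phosphatase 1 to glycogen, showed the largest fall of a named gene, 52.8-fold (-5.72 ± 0.35), ahead of the mitochondrial carrier gene Slc25a30 (-3.72 ± 0.40), Moxd1 (-3.68 ± 1.09), Nrep (-3.49 ± 0.42), Clstn3 (-3.20 ± 0.26), Cyp4a12b (-3.14 ± 0.50), the acyl-CoA thioesterase gene Acot3 (-2.84 ± 0.72) and the keratin gene Krt23 (-2.80 ± 0.27). On treated arrays Ppp1r3g and Acot3 were detected on 4 of 5, Krt23 on 2 and Moxd1 on 1. Other probes moved less, at -2.10 for Ppp1r3g and -0.29 for Clstn3.

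Sterol genes rose and bile acid genes fell in wild-type livers. Of 17 genes of sterol synthesis and uptake 11 rose (11 up and 1 down adjusted over the list alone), with a median of 0.68 (camera adjusted p = 0.00589; adjusted p = 0.391 with an estimated correlation), including the farnesyl diphosphate synthase gene Fdps (1.36 ± 0.25), Msmo1 (1.11 ± 0.20) and Dhcr7 (1.07 ± 0.16). Srebf2, which encodes their main activator, was at 0.15 ± 0.13 (adjusted p = 0.365), but rose with arrays scaled to equal medians (0.61, adjusted p = 0.00132). Of 22 bile acid genes 11 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.00187; adjusted p = 0.13 with an estimated correlation), whereas Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.31 ± 0.35 (adjusted p = 0.519). Among 12 sterol efflux genes 5 rose and 3 fell (5 and 3 adjusted over the list alone), and the median of -0.21 lay below 0 while the mean (0.46) and the direction in camera were up (adjusted p = 0.453). Abcg1, a cholesterol exporter (2.11 ± 0.21), and Lpl, lipoprotein lipase (2.88 ± 0.23), rose and Abca1 was at -0.19 ± 0.22 (adjusted p = 0.538). Abcg1 was detected on 3 and Abca1 on 2 of 5 untreated arrays. Of 18 cell cycle genes 13 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.72e-05; adjusted p = 0.149 with an estimated correlation), with the replication gene Mcm6 at 2.14 ± 0.17 and the cyclin gene Ccnd1 at 1.47 ± 0.19. Among 20 male-biased liver genes 14 fell (14 down and 1 up adjusted over the list alone; camera adjusted p = 1.12e-05; adjusted p = 0.239 with an estimated correlation). Cyp4a12a was at -2.63 ± 0.33 and Nudt7 at -1.94 ± 0.23.

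Markers of other cell types moved beside these groups in wild-type livers. Of 14 liver endothelial genes 8 rose (10 up and 1 down adjusted over the list alone), and of 19 stellate cell, fibroblast and matrix genes 12 rose (15 adjusted over the list alone), with medians of 0.56 and 0.55 and camera adjusted p of 0.000275 and 6.55e-05. With an estimated correlation their adjusted p was 0.149 and 0.13. Of 17 hepatocyte genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), and the median (-0.02) and the mean (0.02) differed in sign (camera adjusted p = 0.974, up). Of 5 red blood cell genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.204). The haemoglobin gene Hba-a1 rose 4.08-fold (2.03 ± 0.29) and Slc4a1, detected on 1 of 5 untreated arrays, by 2.38 ± 0.27. Alas2, the first enzyme of haem synthesis in red cells, fell by 0.55 ± 0.13, a call lost with arrays scaled to equal medians (adjusted p = 0.0545). Car3, the measured member of the adipose list and abundant in liver too, fell by 2.77 ± 0.31.

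In total 4981 of 12976 genes and unnamed probes passed the threshold in wild-type livers, 2815 up and 2166 down. The count was 5702 with batch as a block, 3871 in batch 1 alone and 3425 in batch 2 alone. The median change in batch 1, in batch 2 and with batch as a block was 2.01, 1.67 and 1.86 for the Kupffer cell list, 1.53, 1.55 and 1.56 for the lipid-associated macrophage list, -1.08, -0.80 and -1.03 for the fatty acid oxidation list and 0.75, 0.57 and 0.68 for the sterol list. Of the changed genes named above, Moxd1 lay beyond every untreated array on 4 of 5 treated arrays and the others on 5 of 5. Scaling arrays to equal medians shifted the median of all genes by 0.257 and called 4984 genes up and 720 down, 87.4% up against 56.5%. Probes for Cyp4a12a and Cyp4a12b, and those for Klra17 and Hba-a1, may bind transcripts of close relatives.

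**Figure D1:**
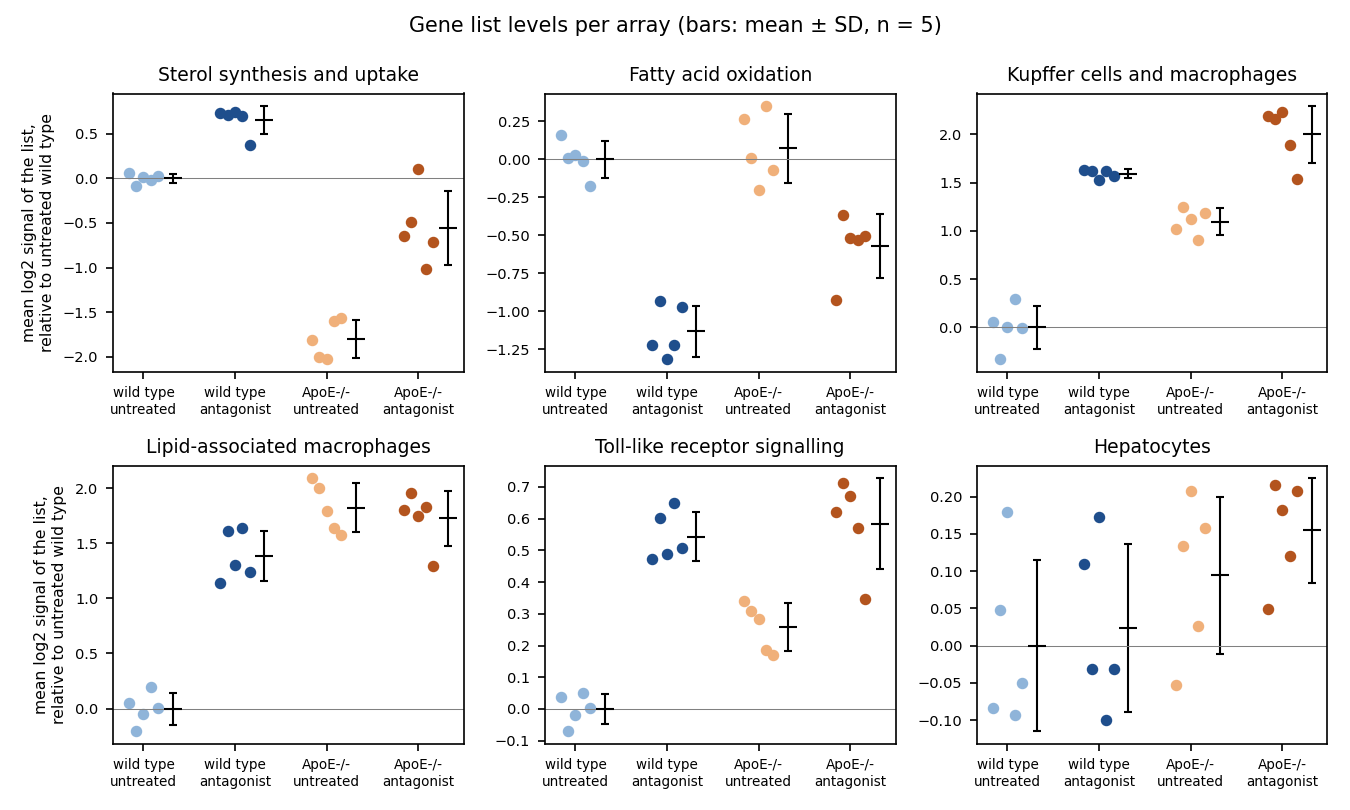
Mean normalised log2 signal of the measured members of 6 fixed gene lists on each array (points), relative to the untreated wild-type mean, with group means ± SD (bars, n = 5) in untreated and antagonist-treated wild-type and ApoE-/- livers. The median change with the antagonist was 1.86 in wild-type and 1.16 in ApoE-/- livers for the Kupffer cell list, and -1.03 and -0.59 for the fatty acid oxidation list.

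Kupffer cell and macrophage genes rose with the antagonist in ApoE-/- livers as well. Among the genes with the largest rises, Fpr2 rose 17.1-fold (4.10 ± 0.31), the lymphocyte and myeloid receptor gene Cd72 16.9-fold (4.08 ± 0.28), Clec4a1 16.8-fold (4.07 ± 0.29), Slamf9 15.8-fold (3.98 ± 0.29) and Fcgr4 15.4-fold (3.94 ± 0.29), each with an adjusted p of 2.18e-08 or less. Klra17 and Clec4b1, below detection on every untreated ApoE-/- array, rose at least 14.1-fold and 9.9-fold, and the cyclin gene Ccnd2 rose 9.87-fold (3.30 ± 0.26). Of 18 Kupffer cell and macrophage genes 12 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 1.3e-05; adjusted p = 0.206 with an estimated correlation), including the scavenger receptor gene Marco (2.44 ± 0.26), Fcer1g (2.69 ± 0.27) and Ctss (1.46 ± 0.16). Among 12 genes of lipid-associated macrophages 4 rose and 2 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.969), with a median of 0.04, a mean of -0.09 and camera's direction up. The integrin gene Itgax rose there (1.99 ± 0.20, detected on 1 of 5 untreated arrays), while Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, fell by 2.62 ± 0.35 and the macrophage elastase gene Mmp12 by 2.61 ± 0.23. Markers of other non-parenchymal cells moved beside these. Of 19 stellate cell, fibroblast and matrix genes 5 rose (6 adjusted over the list alone; camera adjusted p = 0.0276; adjusted p = 0.348 with an estimated correlation), with a median of 0.30, a call lost with the slide as a block (adjusted p = 0.146). Of 14 endothelial genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.148), with a median of 0.23.

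Several immune lists rose in treated ApoE-/- livers, while the neutrophil list did not pass, with 1 of 11 members that rose (1 adjusted over the list alone; camera adjusted p = 0.212). All 9 class II histocompatibility genes measured had a median of 0.94, and 8 of them rose (9 adjusted over the list alone; camera adjusted p = 4.63e-05; adjusted p = 0.166 with an estimated correlation). H2-DMa was at 1.08 ± 0.21 and H2-DMb1 at 1.08 ± 0.20. Among 9 T and NK cell genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00173; adjusted p = 0.166 with an estimated correlation). Cd3e of the T cell receptor complex was at 1.44 ± 0.15 and Thy1 at 1.49 ± 0.17, detected on 1 and 3 of 5 untreated arrays. Of 28 cytokine, chemokine and adhesion genes 16 rose and 1 fell (18 and 2 adjusted over the list alone; camera adjusted p = 3.54e-05; adjusted p = 0.166 with an estimated correlation). Ccl4 was at 3.10 ± 0.32 and Ccl5 at 2.76 ± 0.21. Among 33 interferon-stimulated genes 15 rose (20 up and 1 down adjusted over the list alone; camera adjusted p = 1.13e-05; adjusted p = 0.206 with an estimated correlation). Oas2, detected on 1 of 5 untreated arrays, was at 1.40 ± 0.15 and Ifi27l2a at 1.29 ± 0.16. Among 27 acute phase genes 10 rose (12 adjusted over the list alone; camera adjusted p = 0.00173; adjusted p = 0.313 with an estimated correlation), a call lost with arrays scaled to equal medians (adjusted p = 0.0513). Of 28 Toll-like receptor genes 14 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.00844; adjusted p = 0.166 with an estimated correlation). Myd88 rose by 0.87 ± 0.17 and Unc93b1 by 1.00 ± 0.14, and Tlr5 fell by 1.36 ± 0.18. Tlr7 was at 0.52 ± 0.18 (adjusted p = 0.0342), a call lost with the slide as a block (adjusted p = 0.113), without a detection filter (adjusted p = 0.0684) and without any of 6 single arrays (adjusted p up to 0.103).

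Sterol genes rose in treated ApoE-/- livers. Of 17 genes of sterol synthesis and uptake 14 rose (14 adjusted over the list alone), with a median of 1.05 (camera adjusted p = 1.01e-08; adjusted p = 0.166 with an estimated correlation). Squalene epoxidase, Sqle, detected on 3 of 5 untreated arrays, rose 8.81-fold (3.14 ± 0.37), Fdps 5.14-fold (2.36 ± 0.25), Msmo1 4.30-fold (2.10 ± 0.20) and Srebf2 1.42-fold (0.50 ± 0.13). Cyp7a1 rose 2.04-fold (1.03 ± 0.35, adjusted p = 0.029), a call lost with the slide as a block (adjusted p = 0.0716), without a detection filter (adjusted p = 0.0672), in a fit of the ApoE-/- arrays alone (adjusted p = 0.0743) and without any of 5 single arrays (adjusted p up to 0.0894). Without untreated replicate 1 the change of Cyp7a1 was 0.67. Abca1 was at -0.02 ± 0.22 (adjusted p = 0.958), while Abcg1 rose by 1.13 ± 0.21. Apob and Mttp, which encode the core protein of very low density lipoprotein and the transfer protein that loads it, fell by 0.90 ± 0.12 and 0.76 ± 0.15. They were 2 of 3 falls, beside 4 rises, among 20 lipoprotein genes (4 up and 3 down adjusted over the list alone; camera adjusted p = 0.82). Of 22 bile acid genes 8 fell and 2 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.046; adjusted p = 0.313 with an estimated correlation), a call lost with the replicate number as a block (adjusted p = 0.0603).

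Genes of fatty acid oxidation and lipid droplets fell in treated ApoE-/- livers as well. Of 25 oxidation and ketogenesis genes 17 fell (20 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 1.01e-08; adjusted p = 0.166 with an estimated correlation), including Ehhadh of peroxisomal oxidation (-1.58 ± 0.22) and the ketone enzyme gene Bdh1 (-0.82 ± 0.11). Among 14 lipid droplet genes 8 fell (8 adjusted over the list alone; camera adjusted p = 0.00173; adjusted p = 0.166 with an estimated correlation). G0s2, an inhibitor of lipolysis, was at -2.60 ± 0.45 and the droplet fusion gene Cidec at -2.36 ± 0.45, detected on 4 of 5 treated arrays. Of 22 genes of fatty acid and triglyceride synthesis 4 rose and 4 fell (5 and 4 adjusted over the list alone), with a median of -0.14, a mean of 0.04 and camera's direction down (adjusted p = 0.817). Clstn3 (-3.18 ± 0.26), Krt23 (-3.16 ± 0.27), Slc25a30 (-2.84 ± 0.40), the clock output gene Dbp (-2.56 ± 0.65) and Car3 (-2.38 ± 0.31) were among the largest falls, and another Clstn3 probe was at -0.33. Krt23 was detected on 3 of 5 treated arrays. Of 18 cell cycle genes 13 rose (13 adjusted over the list alone; camera adjusted p = 4.16e-06; adjusted p = 0.166 with an estimated correlation). Mcm6 was at 1.37 ± 0.17 and Ccnd1 at 1.43 ± 0.19. Of 20 fasting and glucose genes 5 fell and 3 rose (6 and 4 adjusted over the list alone), with a median of -0.12, a mean of 0.11 and camera's direction down (adjusted p = 0.642). Among 20 male-biased liver genes 5 fell (5 adjusted over the list alone; camera adjusted p = 0.00844; adjusted p = 0.581 with an estimated correlation). The 17 hepatocyte genes had 4 rises and 2 falls (4 and 2 adjusted over the list alone), with a median of -0.03, a mean of 0.06 and camera's direction up (adjusted p = 0.82). Among 5 red blood cell genes Slc4a1 rose (1.70 ± 0.27, detected on 3 of 5 untreated arrays) and Alas2 fell (-0.52 ± 0.13), the same calls adjusted over the list alone (camera adjusted p = 0.841).

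In total 3842 of 12976 genes and unnamed probes passed in ApoE-/- livers, 2119 up and 1723 down. The count was 4604 with batch as a block, 3510 in batch 1 alone and 1041 in batch 2 alone. In batch 1, in batch 2 and with batch as a block the median change was 1.34, 0.92 and 1.16 for the Kupffer cell list, -0.56, -0.60 and -0.59 for the fatty acid oxidation list, 1.43, 0.50 and 1.05 for the sterol list and 0.16, -0.03 and 0.04 for the lipid-associated macrophage list. The changed genes named lay beyond every untreated ApoE-/- array on all 5 treated arrays, except Tlr7, Myd88, Dbp and H2-DMa on 4 and Cyp7a1 on 3. Apoe itself was at -0.56 ± 0.25 (adjusted p = 0.0963) between treated and untreated ApoE-/- livers, near the low end of the signal, and passed with the replicate number as a block (adjusted p = 0.00655). Scaling to equal medians gave 2360 up and 894 down, 72.5% up against 55.2%.

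The treated and untreated arrays of the 2 genotypes are separate, but all arrays were normalized together and shared 1 estimate of the spread per gene. The calls are thus not independent, and the counts for independent lists below are a rough yardstick and no test. Of the genes and probes tested, 1690 rose in both genotypes, against 459.7 for independent lists, 1169 fell in both, against 287.6, and 9 passed in opposite directions. Across genes, which are not independent replicates, the changes had a Pearson correlation of 0.82. Of 2868 passing in both, 1943 had a smaller change in ApoE-/- livers, the median ratio of ApoE-/- to wild-type change was 0.837, and the slope of the ApoE-/- changes on the wild-type changes was 0.698. Equal effects simulated with independent noise gave a median ratio of 0.989 to 1.01 and a slope of 0.967 to 0.988 in 100 runs. The simulation held no batch, no pairing and no correlation between genes, so these ranges may be too narrow. Without replicate 5 of treated ApoE-/- the ratio was 0.912 and the slope 0.761. Averaged over genotypes, Fpr2 rose by 4.80 ± 0.22, Clec4a1 by 4.73 ± 0.21, Ccl5 by 2.61 ± 0.15, Msmo1 by 1.61 ± 0.14, Thy1 by 1.41 ± 0.12, Tlr7 by 0.94 ± 0.13, Myd88 by 0.85 ± 0.12 and Srebf2 by 0.33 ± 0.09, while Slc25a30 fell by 3.28 ± 0.28 and Clstn3 fell by 3.19 ± 0.18. On that average Cyp7a1 was at 0.36 ± 0.25 (adjusted p = 0.248). That average passed for 6098 genes and probes, 3334 up and 2764 down. It passed for 6710 with batch as a block, 5410 in batch 1 and 4061 in batch 2. Scaling to equal medians shifted the median of all genes by 0.158 with 81.3% up against 54.7%. Sterol genes rose on average (14 of 17; 14 adjusted over the list alone; camera adjusted p = 1.17e-05; adjusted p = 0.171 with an estimated correlation).

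**Figure D2:**
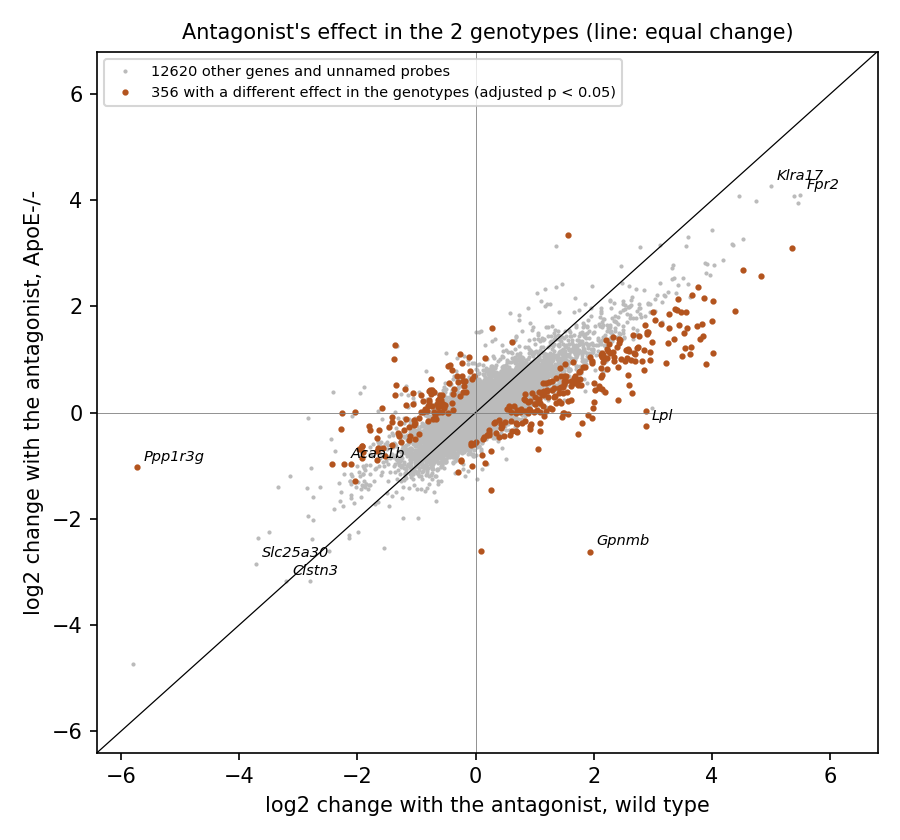
Log2 change with the antagonist in wild-type livers (x axis) against that in ApoE-/- livers (y axis) for each gene or unnamed probe tested, 5 arrays a group, with the 356 whose effect differed between genotypes in colour and a line of equal change. Gpnmb and Lpl rose in wild-type livers without a rise in ApoE-/- livers, and Ppp1r3g fell by 5.72 in wild-type livers.

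Macrophage genes rose less in ApoE-/- than in wild-type livers when the difference itself was tested. The endothelial, stellate cell and matrix, neutrophil and acute phase lists had lower changes too, by camera calls lost with an estimated correlation (values in the closing section). The change of Gpnmb was lower in ApoE-/- livers by 4.56 ± 0.50 log2 units, that of Lpl by 3.13 ± 0.33 and that of the galectin gene Lgals3 by 2.98 ± 0.33 (adjusted p = 3.61e-05 for each, with signs -4.56, -3.13 and -2.98). Mean Gpnmb signal went from 4.89 to 6.83 with treatment in wild-type and from 10.70 to 8.08 in ApoE-/- livers, and Lpl from 8.20 to 11.08 and from 11.17 to 10.92. In untreated wild-type livers Gpnmb was detected on 2 of 5 arrays, Mmp12 on 1, Ccl4 on 3 and S100a8 on 4. Mmp12 (-2.71 ± 0.33), the lipocalin gene Lcn2 (-2.89 ± 0.56), the serum amyloid gene Saa3 (-2.84 ± 0.50), Ear3 (-2.52 ± 0.32), Bcl2a1d (-2.46 ± 0.40) and S100a8 (-2.16 ± 0.50) were lower likewise. Of 12 lipid-associated macrophage genes 6 had a lower change in ApoE-/- livers (7 adjusted over the list alone), with a median of -1.17 (camera adjusted p = 5.36e-11), and this call held with an estimated correlation (adjusted p = 0.0228). Of 18 Kupffer cell genes 8 had a lower and 1 a higher change (10 and 1 adjusted over the list alone; camera adjusted p = 1.85e-07; adjusted p = 0.194 with an estimated correlation), including the lysozyme genes Lyz1 (-1.51 ± 0.16) and Lyz2 (-1.49 ± 0.17), whose probes may bind both, and Ctss (-1.20 ± 0.22). Among cytokine and chemokine genes 5 of 28 had a lower change (7 adjusted over the list alone; camera adjusted p = 9.22e-05; adjusted p = 0.194 with an estimated correlation). Cxcl1 was at -2.28 ± 0.29 and Ccl4 at -2.26 ± 0.45. The changes of Tlr2 (-1.81 ± 0.30) and of Hba-a1 (-1.59 ± 0.40, adjusted p = 0.0358) were lower as well. The latter call was lost with the slide as a block (adjusted p = 0.124) and without any of 15 of the 20 arrays.

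Genes whose change was higher in ApoE-/- than in wild-type livers included some of the fasting and fatty acid oxidation lists. Ppp1r3g had the largest such difference (4.70 ± 0.50, adjusted p = 3.61e-05), with mean signals of 11.11 untreated and 5.39 treated in wild-type against 11.38 and 10.36 in ApoE-/- livers. It and Fosb were detected on 4 of 5 treated wild-type arrays. The early response genes Ccn1 (1.87 ± 0.41) and Fosb (2.63 ± 0.62, adjusted p = 0.0237, and 0.0565 without a detection filter), the carrier gene Slc25a25 (2.05 ± 0.37), G6pc (1.98 ± 0.28) and Depp1 (1.68 ± 0.37) followed. Of 17 immediate early genes 1 had a higher change (4 adjusted over the list alone; camera adjusted p = 0.00531; adjusted p = 0.349 with an estimated correlation). The stress gene Gadd45a (2.25 ± 0.61, adjusted p = 0.0497) and the clock-linked gene Noct (1.70 ± 0.45, adjusted p = 0.0419) each lost the call without any of 16 of the 20 arrays. Of 20 fasting and glucose genes 2 had a higher change (5 adjusted over the list alone; camera adjusted p = 6.04e-06), a call that held with an estimated correlation (adjusted p = 0.0228). Of 25 fatty acid oxidation genes 4 did (9 adjusted over the list alone; camera adjusted p = 1.31e-07; adjusted p = 0.194 with an estimated correlation), among them Acaa1b (1.25 ± 0.21) and Ppara (0.84 ± 0.18). The call of Ppara was lost with arrays scaled to equal medians (adjusted p = 0.0998). Of 17 sterol genes 1 did (8 adjusted over the list alone; camera adjusted p = 5.26e-06; adjusted p = 0.194 with an estimated correlation). Cyp7a1 differed by 1.34 ± 0.49 (adjusted p = 0.163) and Tlr7 by -0.84 ± 0.25 (adjusted p = 0.0867), and both passed with the replicate number as a block (adjusted p = 0.0276 and 0.0489). Apob had a lower change (-0.65 ± 0.17, adjusted p = 0.0496), a call lost with the replicate number as a block (adjusted p = 0.0504), with arrays scaled to equal medians (adjusted p = 0.0764), without a detection filter (adjusted p = 0.0738) and without any of 15 of the 20 arrays. Srebf2 (0.35 ± 0.18, adjusted p = 0.351) and Myd88 (0.05 ± 0.24, adjusted p = 0.955) did not pass.

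In total 356 genes and unnamed probes differed in their response, 115 with a higher and 241 with a lower change in ApoE-/- livers. Of these, 221 had risen in wild-type livers and rose less, or not at all, in ApoE-/- ones, and 92 had fallen and fell less or not at all. The count was 581 with the replicate number as a block, 547 with batch as a block, 147 in batch 1 alone and 238 in batch 2 alone, and 569 with array weights. In batch 1, in batch 2 and with batch as a block the median difference was -0.97, -1.42 and -1.17 for the lipid-associated macrophage list, -0.71, -0.97 and -0.81 for the Kupffer cell list, 0.43, 0.34 and 0.37 for fatty acid oxidation and 0.83, 0.21 and 0.55 for sterol synthesis. Leaving out replicate 1 of treated ApoE-/- gave 571 and leaving out replicate 4 of treated wild type gave 237. Scaling to equal medians shifted the median of all genes by -0.195 and gave 31 higher and 518 lower, 5.65% higher against 32.3%.

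**Figure D3:**
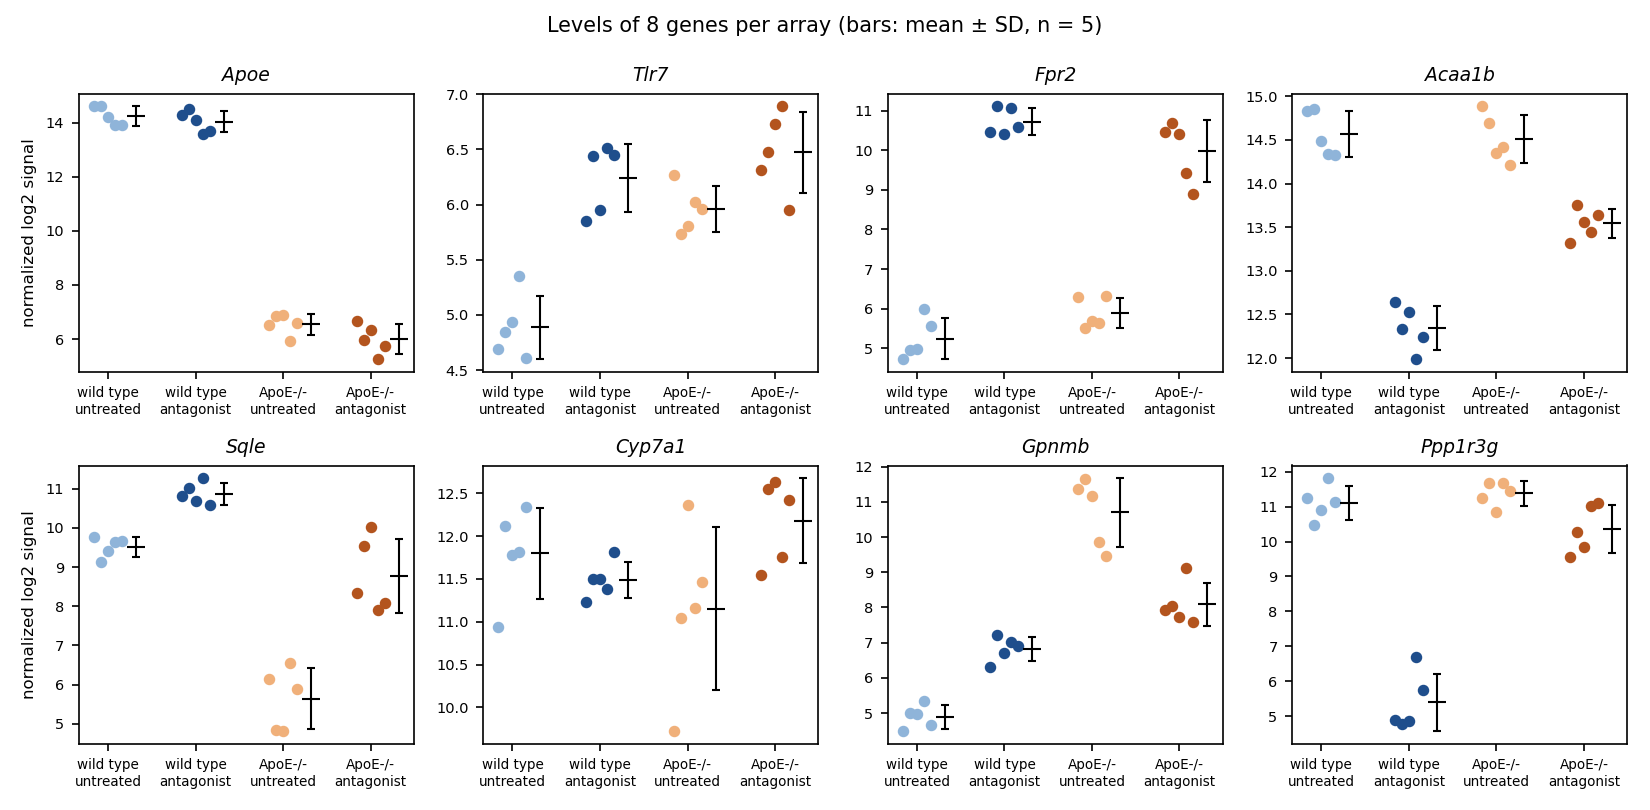
Normalised log2 signal of 8 genes on each array (points) with group means ± SD (bars, n = 5) in untreated and antagonist-treated wild-type and ApoE-/- livers. Gpnmb rose from 4.89 to 6.83 in wild-type livers and fell from 10.70 to 8.08 in ApoE-/- livers, and Ppp1r3g fell from 11.11 to 5.39 in wild-type livers.

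Without treatment, ApoE-/- livers had higher macrophage genes and lower sterol genes than wild-type livers, with diet formula differing beside genotype. Matrix and endothelial markers were higher there too, as given under the other observations. Apoe was 207-fold lower (-7.69 ± 0.25, adjusted p = 1.73e-14). Saa3 was 9.83-fold higher (3.30 ± 0.35), Lpl 7.80-fold (2.96 ± 0.23), Lcn2 7.20-fold (2.85 ± 0.39), Lgals3 6.99-fold (2.80 ± 0.23) and Trem2, a lipid receptor of macrophages, 6.55-fold (2.71 ± 0.27, detected on 3 of 5 wild-type arrays). Gpnmb (5.81 ± 0.35), the steroid hydroxylase gene Cyp2a4 (4.85 ± 0.44) and Mmp12 (3.48 ± 0.23) were higher too, over wild-type signals detected on 2, 1 and 1 of 5 arrays, so that the size of these differences depends on levels near background. Of 12 lipid-associated macrophage genes 7 were higher (8 adjusted over the list alone), with a median of 1.25, and of 18 Kupffer cell genes 15 were higher and 1 lower (15 and 1 adjusted over the list alone), with a median of 1.35 (camera adjusted p = 6.48e-19 and 4.59e-23; adjusted p = 0.0021 and 0.00622 with an estimated correlation). Lyz1 (2.54 ± 0.12) and Lyz2 (2.52 ± 0.12) were among the higher ones and Cd163, a scavenger receptor of resident macrophages, was lower by 4.29-fold (-2.10 ± 0.20, detected on 4 of 5 ApoE-/- arrays). Vcam1 (1.89 ± 0.17), Cxcl1 (1.54 ± 0.21) and Tnfaip3 (1.64 ± 0.22, detected on 2 of 5 wild-type arrays) belonged to 12 of 28 cytokine, chemokine and adhesion genes that were higher (12 adjusted over the list alone; camera adjusted p = 5.66e-10; adjusted p = 0.0315 with an estimated correlation). Class II genes were higher in 6 of 9 (7 up and 1 down adjusted over the list alone; camera adjusted p = 9.38e-07; adjusted p = 0.0459 with an estimated correlation). H2-Ab1 was at 1.18 ± 0.22 and Cd74 at 1.09 ± 0.21. Tlr7 was higher by 1.07 ± 0.18, detected on 1 of 5 wild-type arrays, with Tlr2 (1.53 ± 0.21) and Cd14 (1.64 ± 0.23, detected on 4 of 5), in a list with 6 of 28 members higher (6 adjusted over the list alone; camera adjusted p = 0.0294; adjusted p = 0.223 with an estimated correlation).

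Of 17 sterol genes 16 were lower in untreated ApoE-/- livers (17 adjusted over the list alone), with a median of -1.59 (camera adjusted p = 2e-38; adjusted p = 0.0021 with an estimated correlation). Sqle was 14.7-fold lower (-3.88 ± 0.37), Idi1 8.15-fold (-3.03 ± 0.29), Cyp51 6.95-fold (-2.80 ± 0.26), Msmo1 6.79-fold (-2.76 ± 0.20), Fdps 6.53-fold (-2.71 ± 0.25), Nsdhl 4.61-fold (-2.20 ± 0.21) and the sterol carrier gene Stard4 3.84-fold (-1.94 ± 0.16). Sqle and Nsdhl were detected on 3 of 5 ApoE-/- arrays. Srebf2 was at -0.52 ± 0.13 (adjusted p = 0.014), a call lost with arrays scaled to equal medians (adjusted p = 0.192). The proteasome gene Psmd8 was 6.89-fold lower (-2.78 ± 0.12). Both it and Cyp2a4 lie near Apoe on chromosome 7, 90 and 44 tested genes away. Of 12 sterol efflux genes 5 were higher (6 adjusted over the list alone; camera adjusted p = 2.25e-06; adjusted p = 0.007 with an estimated correlation), including Abcg1 (1.51 ± 0.21, detected on 3 of 5 wild-type arrays) and the desaturase gene Scd1 (1.01 ± 0.19). Abca1 was at 0.04 ± 0.22 (adjusted p = 0.952), Cyp7a1 at -0.65 ± 0.35 (adjusted p = 0.379) and Myd88 at -0.23 ± 0.17 (adjusted p = 0.573). Fatty acid oxidation genes had 1 of 25 higher (2 adjusted over the list alone), with a median of -0.03, a mean of 0.07 and camera's direction down (adjusted p = 0.867). Of 17 hepatocyte genes none passed over all genes or adjusted over the list alone (camera adjusted p = 0.394).

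In total 716 genes and probes differed between the untreated genotypes, 536 higher and 180 lower in ApoE-/- livers. The count was 995 with batch as a block, 633 in batch 1 alone and 146 in batch 2 alone. In batch 1, in batch 2 and with batch as a block the median was -1.55, -1.44 and -1.59 for the sterol list, 1.40, 0.88 and 1.35 for the Kupffer cell list and 1.33, 1.37 and 1.25 for the lipid-associated macrophage list. Each gene named here as different lay beyond every wild-type array on all 5 ApoE-/- arrays. Scaling to equal medians gave 86.2% higher against 74.9%, and another Gpnmb probe moved less.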

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

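Tests chosen only after the result was seen were those of a lower hepatocyte share, of Hba-a1 in ApoE-/- mice, of each batch alone, of the genotype difference among treated mice, of the genes next to Apoe, of simulated equal effects, of splits with the average effect of the antagonist taken off and of splits within pairs or batches.

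An array stood apart from the other 4 of its group, by a gap of over 0.71 of the group's range, in 26 of 492 groups of gene levels, list levels and array measures, where chance gives about 1 in 20, or 24.6. Replicate 1 of treated ApoE-/- held 7 of them, with gaps as a share of the range of 0.76 for the immediate early list, 0.806 for Bdh1, 0.737 for Dbp, 0.807 for Depp1, 0.849 for Gadd45a, 0.84 for Slc25a25 and 0.754 for Slc4a1. Other treated ApoE-/- arrays stood apart in the plasmacytoid dendritic cell list (0.864), the pancreas list (0.729), the drug-metabolising enzyme list (0.743) and Gpnmb (0.717). In treated wild-type livers this held for the sterol list (0.872), Cpt2 (0.816), Srebf2 (0.733) and Moxd1 (0.939). In untreated wild-type livers it held for the bile acid list (0.716), the male-biased list (0.791), G6pc (0.844), Krt23 (0.755), Moxd1 (0.745), Mt1 (0.767), Slc25a25 (0.804) and Slc4a1 (0.776). In untreated ApoE-/- livers it held for the T and NK cell list (0.711), Cd14 (0.767) and Noct (0.733).

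The effect of the antagonist differed between genotypes, by a test of the difference itself, for 356 genes and probes. Among the named genes the log2 change in ApoE-/- minus that in wild-type livers was 4.70 for Ppp1r3g, 2.63 for Fosb, 2.25 for Gadd45a, 2.05 for Slc25a25, 1.98 for G6pc, 1.87 for Ccn1, 1.70 for Noct, 1.68 for Depp1, 1.25 for Acaa1b and 0.84 for Ppara. It was -4.56 for Gpnmb, -3.13 for Lpl, -2.98 for Lgals3, -2.89 for Lcn2, -2.84 for Saa3, -2.71 for Mmp12, -2.52 for Ear3, -2.46 for Bcl2a1d, -2.28 for Cxcl1, -2.26 for Ccl4, -2.16 for S100a8, -1.81 for Tlr2, -1.59 for Hba-a1, -1.51 for Lyz1, -1.49 for Lyz2, -1.20 for Ctss and -0.65 for Apob. Lists with a higher change in ApoE-/- livers had camera adjusted p of 5.26e-06 (sterol synthesis), 0.0454 (bile acids), 0.00215 (fatty acid synthesis), 1.31e-07 (fatty acid oxidation), 0.0255 (T and NK cells), 0.000114 (male-biased genes), 0.0106 (circadian clock), 6.04e-06 (fasting and glucose), 0.00049 (heat shock), 0.00531 (immediate early genes) and 0.04 (complement and coagulation). Lists with a lower change had 0.0109 (interferon-stimulated genes), 9.22e-05 (cytokines and chemokines), 3.17e-05 (acute phase), 1.85e-07 (Kupffer cells), 5.36e-11 (lipid-associated macrophages), 0.000216 (neutrophils), 9.35e-06 (endothelial cells), 0.000602 (stellate cells and matrix) and 0.0436 (ribosomal proteins). With an estimated correlation the lipid-associated macrophage and the fasting lists kept their calls (adjusted p = 0.0228 for both), and the other 18 of these 20 lists lost theirs (adjusted p = 0.194 to 0.555).

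The Kupffer cell and macrophage list rose and the fatty acid oxidation list fell with the antagonist in both genotypes, by camera with the preset correlation. With an estimated correlation neither passed (adjusted p = 0.13 and 0.129 in wild-type, 0.206 and 0.166 in ApoE-/- livers). The lipid-associated macrophage list rose in wild-type but not in ApoE-/- livers (medians 1.56 and 0.04), and below the macrophage list is the Kupffer cell and macrophage one. A lower share of hepatocytes in treated livers would lower all hepatocyte genes and raise every other cell type alike. The hepatocyte list's median lay above that of the oxidation list by 1.02 in wild-type and 0.56 in ApoE-/- mice (permutation p = 0.00013 and 0.00078). The macrophage list's median lay above that of 39 endothelial, stellate and bile duct genes by 1.39 and 0.894 (permutation p = 0.00035 and 0.00019). These permutations exchange genes as if independent and do not measure the spread between livers. The 39 genes themselves had medians of 0.472 and 0.262. The values argue against a lower hepatocyte share as the whole cause and leave open a part of it. Blood left in the tissue would carry haemoglobin transcripts. In ApoE-/- mice Hba-a1 changed by 0.436 ± 0.286 (SE) beside a macrophage median of 1.16, which argues against blood as the whole cause there. Slc4a1, a dim red cell gene detected on 3 of 5 untreated arrays there, still rose by 1.70 ± 0.27. In wild-type mice Hba-a1 rose by 2.03 ± 0.286, more than the macrophage median of 1.86, as it would with blood. Of 5 red blood cell genes 3 rose and 1 fell there. With each array's Hba-a1 level as a covariate 105% of that median was left (1.96 against 1.86, with 13 of 18 genes rising and 1420 genes past the threshold). The covariate's slope comes from the spread within groups. Only if it holds between groups does this argue against blood as the whole cause in wild-type mice. Each batch held as many treated as untreated arrays of each genotype, so batch alone could not give these changes. The smaller of the batches' medians was at least 0.686 of the larger for both lists in both genotypes. In batch 2 treated ApoE-/- arrays were on slide 1 and untreated ones on slide 2, so slide cannot be told apart from antagonist there. More macrophages and higher expression in each macrophage both stay open as biological hypotheses, and neither was tested.

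The response was smaller in ApoE-/- mice, with a median ratio of 0.837 and a slope of 0.698 against the wild-type changes over genes called in both. Simulated equal effects, with noise independent between genes, gave 0.989 to 1.01 and 0.967 to 0.988. Batch and pairing were left out of the simulation, so its ranges may be too narrow. Replicate 5 of treated ApoE-/- lay nearest to the untreated arrays, but without it the slope was 0.761, the ratio 0.912 and 280 genes still differed in response, which argues against that array as the whole cause and leaves open a part of it; the slope over the same genes was 0.797 in batch 1 and 0.527 in batch 2. Whether macrophage genes responded less because they were higher without treatment stays open: the median genotype difference of the lipid-associated macrophage list was 1.25 among untreated and 0.185 among treated mice, and that of the Kupffer cell list 1.35 and 0.295, but the second value of each pair follows from the first and the smaller response, so it tests nothing. The diet formula, which differed with genotype, stays open and untested.

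Genes next to Apoe were over-represented among the differences between untreated genotypes. Of the 200 tested genes nearest to Apoe, 100 on each side, 33 passed (19 higher and 14 lower in ApoE-/-), against a median of 12 and a highest count of 20 in 626 other windows of that size, which overlap with one another. Of these, 17 of 33 passed in the same direction among treated mice, against 92 of 574 other called genes (Fisher's exact p = 6.3e-06, two-sided) in a fit where all arrays shared 1 estimate of the spread, as with Clasrp (-1.54 untreated, -1.96 treated, detected on 3 and 2 of 5 ApoE-/- arrays), Sae1 (1.64, 1.27), Mrps12 (-1.18, -1.43), Psmd8 (-2.78, -3.15) and Cyp2a4 (4.85, 6.15, detected on 1 and 4 of 5 wild-type arrays), examples chosen after their values were seen. DNA of another strain that came with the targeted allele stays open as a source: with untreated and treated arrays fitted apart, 28 neighbours were called (highest other window 19), of which 13 of 28 passed again among treated mice, against 82 of 525 others (Fisher's exact p = 0.000209, two-sided), but most did not, and real expression differences were not told apart from mismatches under probes. Regulation by cholesterol or inflammation stays open as well, since 42.4% of the called neighbours changed with the antagonist in ApoE-/- mice against 52.8% of other called genes (Fisher's exact p = 0.284, two-sided).

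Other splits of the arrays tested whether chance alone gives such counts, with 100 splits for each contrast, the real one included. For the antagonist in wild-type mice 1 of 100, the real one with 4981 genes, reached that count (highest other 1443). In ApoE-/- mice it was 1 of 100 (3842, highest other 2054) and for the average 1 of 100 (6098, highest other 3478). For the untreated genotypes it was 1 of 100 (716, highest other 11). Chance is thus unlikely for these if arrays can be exchanged freely. For the difference in response 3 of 100 splits reached 356 and the highest other gave 3368, several times the real count. That points to the structure of the samples, since a split that nearly exchanges treated and untreated arrays in 1 genotype turns the difference into the antagonist's effect itself, so these splits do not test the difference. With each gene's average effect of the antagonist taken off the treated arrays, which leaves the difference and the residuals as they were, 1 of 100 splits reached 356 (highest other 0). All these splits exchange arrays freely across replicate numbers, which were taken to pair treated with untreated arrays, and across batches. Among 100 splits that part every such pair and so keep each batch even, with the average effect taken off, 1 of 100 again reached 356 (highest other 0). Chance is thus unlikely for the difference if the numbers do pair the arrays, which is uncertain. The difference left in the treated arrays adds to the spread in the other splits, which lowers their counts. Splits that part every pair, on the values as measured, gave a highest other of 2445 for the average in 100 splits, and splits of the untreated genotypes even within batches a highest other of 7 in 60 splits. In each genotype alone only 16 splits part every pair, too few for a share under 0.05, with a highest other of 1 in wild-type and 1184 in ApoE-/- mice.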

How the results depend on the processing

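Batch as a block and each batch alone were chosen after seeing the data; the other alternatives were not. Of 522 values of genes that the naming rule picked, 449 kept their direction and their side of the threshold under every alternative, other than those of batch, that gave them a value, and stricter filters and a fit of fewer groups gave some of them none. With all probes only the probe with the smallest p counted, so a discordant second probe could not count against a gene. Many of these genes were picked for large changes or small p in the same data, so this does not speak for other genes. Signal over background limits dim genes: calls on probes detected on few arrays of a group rest on values near the floor. Over the lists and contrasts, 102 results passed with the preset correlation and 11 with the correlation estimated per list. The 2 runs differed only in that setting, so the calls that were lost rest on the preset of 0.01. Preset p-values are too small for lists whose genes correlate more than that. Reversals came in batch 2 alone, with 2 arrays a group. There the list of female-biased liver genes turned lower for the difference in response (adjusted p = 0.0254), interferon-stimulated genes turned lower between untreated genotypes (adjusted p = 0.782) and Hspb1 in ApoE-/- mice moved from -0.93 (adjusted p = 0.0255) to 0.05 (adjusted p = 0.901). The cause of these was not tested.

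Asking for a fold of at least 1.5, which only removes genes, gave 2699 for wild-type mice (from 4981), 1926 for ApoE-/- mice (from 3842) and 2235 for the average (from 6098). Batch 2 alone, with fewer arrays, gave 1041 for ApoE-/- mice, 4061 for the average and 146 for the untreated genotypes (from 716). For the difference in response, 356 became 147 in batch 1 alone, 547 with batch as a block, 569 with array weights and 549 with scaling to equal medians, and it was 238 in batch 2 alone. The cause of these was not tested. With the replicate number as a block, where the numbers were taken to pair treated with untreated arrays, it became 581. Cyp7a1 and Tlr7 then passed for that difference, Apob lost its call there (adjusted p = 0.0504) and Apoe passed in ApoE-/- mice (adjusted p = 0.00655). The bile acid list lost its call in ApoE-/- mice (adjusted p = 0.0603) and the B and plasma cell list in wild-type mice (adjusted p = 0.0508). That list and the plasmacytoid dendritic cell list gained one in ApoE-/- mice (adjusted p = 0.047 for both). Of the calls that the text gives for these contrasts, the block changed no other. For the untreated genotypes, whose numbers were not taken to pair the samples, the block gave 993. There 4 of the samples correlated best with their own number, as many as between treated and untreated arrays in each genotype.

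Leaving out each array in turn gave 4504 to 5102 genes for wild-type mice, 3250 to 4213 for ApoE-/- mice, 5785 to 6218 for the average, 237 to 571 for the difference in response and 578 to 787 for the untreated genotypes. The 237 came without replicate 4 of treated wild type and the 571 without replicate 1 of treated ApoE-/-. Cyp7a1 in ApoE-/- mice lost its call without untreated replicate 1 (0.67 from 1.03, adjusted p = 0.0894) or 2 (0.0551) or treated replicate 2 (0.0734), 3 (0.0763) or 5 (0.054), within 0.00241 to 0.0894 over the alternatives other than those of batch that gave it a value, as are the ranges that follow. Tlr7 in ApoE-/- mice lost it without untreated replicate 2 (adjusted p = 0.0837), 3 (0.0735) or 5 (0.0552) or treated replicate 2 (0.0604), 3 (0.0911) or 4 (0.103), within 0.00242 to 0.113. Fosb lost its difference in response without untreated wild-type replicate 3 (adjusted p = 0.0507, within 0.00367 to 0.0565). Gadd45a and Noct lost theirs in 16 of 20 such fits each and Hba-a1 and Apob in 15 of 20 each (within 0.000237 to 0.136, 0.00541 to 0.1, 0.00568 to 0.124 and 0.0196 to 0.103). Apoe in ApoE-/- mice passed without untreated replicate 4 (adjusted p = 0.0362) or treated replicate 1 (0.0302), within 0.00655 to 0.287. The difference for Tlr7 passed without untreated wild-type replicate 4 (0.0405) or treated wild-type replicate 1 (0.0486), within 0.0374 to 0.278.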

Other observations

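The comparison between treated genotypes was chosen after the other results were seen. Of 28 cytosolic ribosomal protein genes 22 rose and 1 fell with the antagonist in wild-type livers (23 and 1 adjusted over the list alone, camera adjusted p = 8.81e-07, and 0.149 as the adjusted p with an estimated correlation). In ApoE-/- livers 19 rose (20 adjusted over the list alone, camera adjusted p = 4.72e-06, adjusted p = 0.238 with an estimated correlation). Heat shock genes fell in wild-type livers, 9 of 13 (9 adjusted over the list alone, camera adjusted p = 0.00127, adjusted p = 0.162 with an estimated correlation). In ApoE-/- livers 3 of 13 fell (5 down and 1 up adjusted over the list alone, camera adjusted p = 0.529). Of 17 immediate early genes 8 rose and 1 fell in ApoE-/- livers (11 and 1 adjusted over the list alone, camera adjusted p = 0.00251, adjusted p = 0.315 with an estimated correlation). In wild-type livers 5 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of -0.05, a mean of 0.14 and camera's direction up (adjusted p = 0.657). The steroid 17-alpha-hydroxylase gene Cyp17a1 rose 7.19-fold in wild-type (2.85 ± 0.32 SE, n = 5 a group) and 4.95-fold in ApoE-/- livers (2.31 ± 0.32), with limma adjusted p of 4.87e-07 and 1.87e-05. Cyp2a4, higher in untreated ApoE-/- livers, rose a further 3.68-fold with the antagonist there (1.88 ± 0.44). Probe ILMN_2835423, which the table used here does not name, fell in both genotypes, from detection on all untreated arrays to detection on 1 of 5 treated wild-type and 4 of 5 treated ApoE-/- arrays (-5.80 and -4.73), so that the size of the wild-type fall depends on background.

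Between untreated genotypes, matrix and endothelial markers were higher in ApoE-/- livers. This held for 7 of 19 stellate cell, fibroblast and matrix genes (8 adjusted over the list alone, camera adjusted p = 6.56e-06, adjusted p = 0.0528 with an estimated correlation), with the collagen gene Col3a1 at 1.52 ± 0.16. It held for 7 of 14 endothelial genes too (9 adjusted over the list alone, camera adjusted p = 2.22e-07), a call that held with an estimated correlation (adjusted p = 0.0493). Neutrophil genes were higher in 3 of 11 (3 adjusted over the list alone, camera adjusted p = 0.00187, adjusted p = 0.223 with an estimated correlation) and acute phase genes in 6 of 27 (8 adjusted over the list alone, camera adjusted p = 1.77e-05, adjusted p = 0.136 with an estimated correlation). Haem oxygenase, Hmox1, was 2.88-fold higher (1.53 ± 0.27) and the drug-metabolising gene Cyp3a11 2.51-fold higher (1.33 ± 0.26), while Cela1 of the pancreas list was 2.39-fold lower (-1.26 ± 0.17). Among treated mice 659 genes and probes differed between genotypes, 380 higher and 279 lower in ApoE-/- livers. There Gpnmb stayed higher (1.25 ± 0.35, adjusted p = 0.0436), while Mmp12 (0.78 ± 0.23, adjusted p = 0.0547), Trem2 (0.72 ± 0.27, adjusted p = 0.139), Lpl (-0.17 ± 0.23, adjusted p = 0.816), Lgals3 (-0.18 ± 0.23, adjusted p = 0.798) and Lcn2 (-0.05 ± 0.39, adjusted p = 0.981) did not pass. Sqle (-2.09 ± 0.37), Fdps (-1.71 ± 0.25) and Msmo1 (-1.77 ± 0.20) were lower, and Lyz1 (1.04 ± 0.12) and Ppp1r3g (4.97 ± 0.35) were higher.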
